A study of Mus musculus with 9 samples.

How the data were processed

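The series holds bulk RNA sequencing of mouse (Mus musculus) vaginal epithelial tissue from 3 groups: control, a mouse model of vulvovaginal candidiasis (VVC, a Candida yeast infection of the vulva and vagina) and a model of its recurrent form (RVVC), with 3 libraries per group. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA-Seq kit. The labels name no strain, age, cycle stage, Candida isolate, dose or time of collection, and nothing says that the libraries of a group came from separate animals. The p-values therefore measure the spread between these libraries, which may be partly technical.

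The deposited table lists 34005 Ensembl genes with, per the file headers, a read count and an FPKM value (fragments scaled by transcript length and library total) for each of the 9 libraries. The aligner, the counter, the genome build and the handling of reads that match several genes are not given in the sources used here. The gene coordinates were compared with the GENCODE M21 annotation of GRCm38: 33894 gene IDs were found there, 30920 with the same start and end and 33892 overlapping. Coordinates are printed as the deposited table gives them. Each column was matched to its sample by the library name in the labels, and 0 columns of per-sample values were left unused. An FPKM of 0 stood beside a count above 0 in 31 values, and an FPKM above 0 beside a count of 0 in 0 values.

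The deposited counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with the groups given (21384 genes), libraries were scaled with TMM factors, and a negative binomial model with group as the term was fitted to all 9 libraries at once (estimateDisp, glmQLFit with the package's default estimate, glmQLFTest), which leaves 6 residual degrees of freedom. The 3 comparisons were VVC against control, RVVC against control and RVVC against VVC, each tested in both directions, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan, written before the data were examined, set this test for a table with counts and limma on log2(FPKM + 1) for a table without. The alternatives planned on FPKM were accordingly run as limma 3.58.1 fits on the deposited FPKM (genes with an FPKM of at least 1 in at least 3 libraries), and the planned FPKM filters and median-ratio scaling were also run on the counts. Log2 fold changes are given with an SE, computed as the absolute log2 fold change divided by the square root of the test's F statistic. CPM (counts scaled to the TMM library total) are given as mean ± SD.

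A total of 39 gene lists with 801 entries was fixed before the data were examined, covering immune cells and mediators, epithelial states, metabolism, RNA quality and other tissues a vaginal sample could hold. Of the entries, 10 were matched through a RefSeq synonym and 11 were not found in the table. Where 2 or more rows share a symbol, the row with the highest count was used. In the table, 73 rows repeat the symbol of an earlier row. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. They were also tested with a correlation estimated from the data and with fry, whose p asks whether a list's members move, on balance, one way. Members were counted over all genes tested and also adjusted over the list alone. A list level is the mean log2 CPM of its tested members in a library, with a prior count of 2.

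Genes named in the text follow a rule fixed in advance: up to 8 per direction among the genes past the threshold or, since none passed, the 4 with the smallest p per direction, leaving out unnamed models, pseudogenes and antigen receptor segments, up to 4 members with the smallest p from each of the 6 lists with the smallest camera p, and 13 genes in every comparison (S100a8, S100a9, Lcn2, Il1b, Cxcl1, Cxcl5, Il17a, Krt1, Krt13, Krt5, Mki67, Esr1 and Ptprc). Of the genes that this rule names, 1 is left out of the text. A planned test of annotation terms among called genes could not be run because edgeR called 0 genes. In its place, after the data were seen, KEGG and Reactome terms of the deposited table with 10 to 500 tested genes were tested with camera.

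Alternatives planned in advance were DESeq2 1.42.0 with its size factors, other filters, median-ratio scaling, limma on FPKM with pseudocounts of 0.1 and 0.01, quantile normalization, array weights, no variance trend, a block for the replicate number, only the groups compared, and each library left out in turn. limma on log2(FPKM + 1), edgeR's newer quasi-likelihood estimate and the cornified-envelope level as a covariate were added after seeing the data, as was the correlation of fold changes with disjoint controls. Each comparison was refitted on all 10 splits of its 6 libraries. Correlation of the fold changes against the shared controls was set beside 20 simulations of unchanged groups.

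The fit was tested on simulated counts drawn with the means, dispersions and library sizes of these data, each gene independently of the others. At each fold, 50 genes among 21384 were changed. In the simulation of RVVC against control, 66% of 16-fold, 32% of 8-fold, 22% of 4-fold and 0% of 2-fold changes were recovered, with 2 false calls. In that of VVC against control the shares were 54%, 44%, 26% and 0%, with 4 false calls. For RVVC against VVC they were 64%, 58%, 34% and 0%, with 3 false calls. Library totals ran from 54162946 to 63097458 counts, and a floor of 3 counts in a library corresponds to 0.0458 to 0.0580 CPM. The common biological coefficient of variation was 0.606, so the spread between libraries, more than depth, sets the precision.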

Results

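Gene expression was measured by RNA sequencing in vaginal epithelial tissue of control mice, mice with vulvovaginal candidiasis (VVC) and mice with the recurrent form (RVVC), with 3 libraries per group. The series asks which genes differ between the 3 groups. Library totals were 54162946 to 57875380 counts in the control group, 55512566 to 56697847 in VVC and 59035339 to 63097458 in RVVC. Between 24898 and 26192 genes had at least 1 count in a library. Mitochondrially encoded genes took 4.03% to 7.06% of counts in control, 6.02% to 12.8% in VVC and 5.07% to 7.52% in RVVC.

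Libraries of the same group differed strongly in their epithelial genes. The cornified envelope list, the proteins of the keratinised surface layer, had a level of 4.62 log2 CPM in control replicate 3 but -0.52 and -0.03 in the other control libraries. In VVC it was 4.35 and 4.02 in replicates 1 and 2 and -0.14 in replicate 3. In RVVC it was 5.27 in replicate 2, -0.54 in replicate 1 and 0.81 in replicate 3. Basal keratinocyte markers ranged from 4.99 to 8.15 log2 CPM over the 9 libraries and mucous epithelial markers from 2.71 to 5.81. Control replicate 3 also carried skeletal muscle transcripts, at a list level of 6.40 log2 CPM against 0.90 and 0.86 in the other control libraries. The first principal component held 37.1% of the variance, and its values overlapped between the groups, from -114 to 98.6 in control, -109 to 73.7 in VVC and -50.8 to 122 in RVVC.

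**Figure D1:**
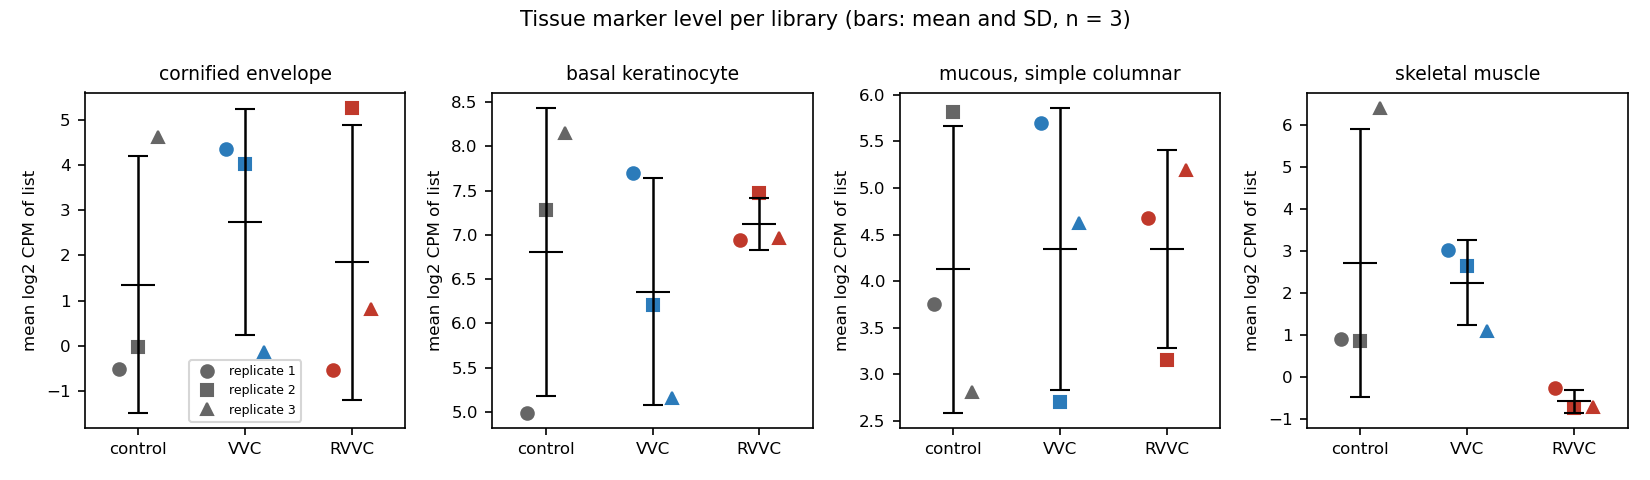
Mean log2 CPM of 4 tissue marker lists (vertical axes) in each library of the 3 groups (horizontal axes). Symbols mark replicates and bars the mean and SD of 3 libraries. The cornified envelope level spans -0.54 to 5.27 within the RVVC group alone, and skeletal muscle reaches 6.40 in control replicate 3.

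VVC against control asks which genes differ between the VVC model and control. The lipocalin Lcn2, an antimicrobial iron-binding protein, averaged 301 ± 397 CPM (SD, n = 3) in VVC and 27.6 ± 25.2 in control, a log2 difference of 3.45 ± 1.37 (SE). S100a8, a calprotectin subunit, averaged 21.1 ± 28.5 and 0.985 ± 0.374 CPM, with a log2 difference of 4.42 ± 2.09. Its partner S100a9 averaged 25.5 ± 35.1 and 1.98 ± 1.31 CPM, with a log2 difference of 3.69. Single libraries carried these differences: Lcn2 reached 758 CPM in VVC replicate 3 against 35.9 and 111 in the other VVC libraries, and its log2 difference was 1.39 without that library. Without VVC replicate 2 the differences were 2.30 for S100a8 and 1.45 for S100a9, and with the cornified level as a covariate they were 1.18 and -0.13. For Il1b, Cxcl1, Cxcl5 and Il17a the log2 differences were 1.02 ± 0.70, 0.62 ± 0.39, 0.74 ± 1.55 and 0.53 ± 1.88. Il1b was 0.60 without control replicate 1 and 1.63 without control replicate 2, and Cxcl1 was 0.38 and 1.13 without these and 0.32 without VVC replicate 2. Cxcl5 turned to -0.44 without VVC replicate 1 and Il17a to -0.72 without VVC replicate 2. The keratins Krt1, Krt5 and Krt13, the proliferation marker Mki67, the oestrogen receptor gene Esr1 and the leukocyte gene Ptprc stood at -1.56 ± 2.56, -1.07 ± 1.62, -0.34 ± 1.66, -0.19 ± 0.83, 0.46 ± 0.32 and 0.52 ± 0.37. Without control replicate 3, Krt1, Krt5, Krt13 and Mki67 turned to 4.25, 0.75, 1.75 and 0.24. Krt13 and Mki67 also turned without VVC replicate 3, to 0.24 and 0.34, and Ptprc was 0.10 without VVC replicate 1. None of these genes passed the threshold, and edgeR's quasi-likelihood test called 0 of 21384 genes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 604 genes, 317 higher and 287 lower, where chance alone gives 1069. DESeq2 called 21 genes, 11 higher and 10 lower, a count that 9 of the 10 splits of the 6 libraries reached, and limma on log2(FPKM + 1) called 1, AI506816.

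AI506816 (ENSMUSG00000105987, chromosome 5, 23698296 to 23712666 on the minus strand), a transcript without an assigned function, had the smallest p of this comparison. It stood at 71.6 ± 24.8 CPM in control and 2.95 ± 2.72 CPM in VVC, a log2 fold change of -4.60 ± 0.67, with an adjusted p of 1 by edgeR and 0.020 by limma. Glypican Gpc3 (-1.13 ± 0.20), Tppp3 (-1.04 ± 0.23) and Cdc42ep4 (-0.57 ± 0.13) were also lower in every VVC library than in any control library, and did not pass. They were picked for their small p, and 6.36% of all genes tested did not overlap between these groups, where chance gives 10%. The smallest p among higher genes belonged to the major urinary protein genes Mup22, Mup13, Mup2 and Mup10, near-identical copies between which reads cannot be assigned with certainty. Mup22 averaged 1.08 ± 0.605 CPM in VVC with 0 counts in all 3 control libraries, at least 18.6-fold higher against a floor of 3 counts in a library. The bounds were at least 9.23-fold for Mup13, 9.24-fold for Mup2 and 11.6-fold for Mup10, the last 7.48-fold without VVC replicate 1.

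Among the fixed gene lists in VVC against control, camera with a preset correlation called 15 of 39, 13 higher and 2 lower. The interferon response list rose, with 26 of 28 members at a positive fold change and a median log2 of 0.76 (adjusted p = 4.3e-07, and adjusted p = 0.37 with an estimated correlation). Its members Gbp2, Bst2 and Zbp1 had log2 differences of 1.2 ± 0.45, 1.12 ± 0.52 and 1.26 ± 0.63, none past the threshold. Gbp2 was 0.60 without VVC replicate 2 and Bst2 0.48 without VVC replicate 3. MHC class II genes, which present peptides to T cells, rose by a median of 0.76 with all 11 members positive (adjusted p = 3.6e-07, and adjusted p = 0.34 with an estimated correlation). H2-DMa, H2-Aa, H2-Ab1 and Cd74 stood at 0.75 ± 0.29, 0.85 ± 0.35, 0.91 ± 0.39 and 0.76 ± 0.34, with H2-Aa at 0.53 without VVC replicate 1 and Cd74 at 0.50 without control replicate 3. Neutrophil and monocyte chemokines rose by a median of 0.95 and the IL-1 and inflammasome list by 0.80, with adjusted p of 0.34 and 0.37 with an estimated correlation. Macrophage markers rose by a median of 0.47 and complement genes by 0.33, both at an adjusted p of 0.37 with an estimated correlation. Without VVC replicate 1 the macrophage call was lost (median 0.25, adjusted p = 0.16) and the chemokine median was 0.41. The chemokine median was 0.55 without control replicate 1, and the interferon median was 0.44 without control replicate 3 and 0.38 without VVC replicate 2.

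Other lists also shifted between VVC and control, but their levels in single libraries overlapped between these groups. Adipocyte genes rose by a median of 1.43 log2, among them Lpl (1.52 ± 0.58), Cfd (2.21 ± 0.96), Retn (1.92 ± 0.92) and Plin4 (1.10 ± 0.58). Smooth muscle genes rose by 1.0 with all 12 members positive, among them Tagln (1.49 ± 0.55), Myl9 (1.05 ± 0.42), Des (1.17 ± 0.56) and Cnn1 (0.92 ± 0.45). Mitochondrially encoded transcripts rose by 0.77, with mt-Nd1, mt-Nd2, mt-Nd4l and mt-Nd5 between 0.83 and 0.88. All 3 lists had an adjusted p of 0.37 with an estimated correlation. The medians were 0.68 for adipocyte genes without VVC replicate 3, and 0.66 for smooth muscle and 0.32 for mitochondrial genes without VVC replicate 2. Without VVC replicate 3, Lpl, Retn and Plin4 were 0.70, 1.06 and 0.41, and Retn was 2.95 without control replicate 2. Without VVC replicate 2, Tagln and Des were 0.90 and 0.63 and the 4 mitochondrial genes 0.41 to 0.55, and mt-Nd5 was 0.58 without control replicate 1. Cell cycle genes fell by 0.32 with all 28 members negative (adjusted p = 0.84 with an estimated correlation), and Mcm6, E2f1, Mcm4 and Tyms stood at -0.77 ± 0.64, -0.51 ± 0.49, -0.39 ± 0.38 and -0.47 ± 0.46. With 1 library left out they ran from -1.58 to -0.29, -1.32 to -0.21, -1.0 to -0.16 and -1.21 to -0.19, lowest without VVC replicate 1 and highest without VVC replicate 3. The cell cycle median was -0.01 without control replicate 3, -1.33 without VVC replicate 1 and -0.12 without VVC replicate 2, and without VVC replicate 3 it turned to 0.13 and the call was lost (adjusted p = 0.74). Immediate early and heat shock genes fell by 0.61 (adjusted p = 0.37 with an estimated correlation), with medians of -0.92 without control replicate 1 and -0.38 without control replicate 2. The cornified envelope, antimicrobial peptide, B cell and urogenital lists were also called higher at the preset correlation, with adjusted p of 0.92, 0.73, 0.84 and 0.37 with an estimated correlation. Each of these calls was lost when single libraries were left out: the cornified call without control replicate 1, control replicate 2 or VVC replicate 1 (adjusted p = 0.43, 0.20 and 0.46), and the antimicrobial call without control replicate 1, control replicate 3 or VVC replicate 1 (adjusted p = 0.40, 0.20 and 0.46). The B cell call was lost without control replicate 2, control replicate 3 or VVC replicate 1 (adjusted p = 0.16, 0.69 and 0.77) and the urogenital call without control replicate 3 or VVC replicate 1 (adjusted p = 0.38 and 0.24). In none of the 39 lists did a member pass over all genes or adjusted over the list alone, no list was called with an estimated correlation, and fry called 0.

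RVVC against control asks which genes differ between the RVVC model and control. Genes of macrophages stood at the top of the ranking, each higher in all 3 RVVC libraries than in any control library. Of all genes tested, 10.1% did not overlap between these groups, where chance gives 10%. Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61131134), the receptor for macrophage colony-stimulating factor, averaged 138 ± 22.8 CPM (SD, n = 3) in RVVC and 47.0 ± 4.67 in control, a log2 fold change of 1.56 ± 0.16 (SE). Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a glycoprotein of macrophages, averaged 499 ± 63.3 against 77.0 ± 28.7 CPM, a log2 fold change of 2.69 ± 0.31. Slc15a3, a lysosomal peptide transporter, and Mpeg1, a pore-forming protein of macrophages, differed by 2.38 ± 0.28 and 1.54 ± 0.20. AI506816 was again far lower, at 3.23 ± 0.314 against 71.6 ± 24.8 CPM (-4.47 ± 0.67), followed by Nab2 (-1.13 ± 0.18), Lcat (-2.06 ± 0.34) and Lig4 (-1.47 ± 0.26).

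None of these single genes passed in edgeR's quasi-likelihood test, which called 0 genes in RVVC against control. The smallest adjusted p was 0.17, shared by Csf1r, Slc15a3 and Gpnmb. At an unadjusted p under 0.05 there were 992 genes, 511 higher and 481 lower, where chance gives 1069. DESeq2 called 242 genes, 144 higher and 98 lower, 9 of them on the macrophage list, and 3 of the 10 splits of the 6 libraries reached that count. limma on log2(FPKM + 1) called 3: Csf1r (adjusted p = 0.036), Gpnmb (adjusted p = 0.013) and AI506816 (adjusted p = 0.013). Among genes with a mean FPKM of at least 5, edgeR called Csf1r alone (adjusted p = 0.035). Without control replicate 2 it called only Saa3, a serum amyloid gene (adjusted p = 0.044), which is outside the naming rule and was chosen after its values were seen.

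**Figure D2:**
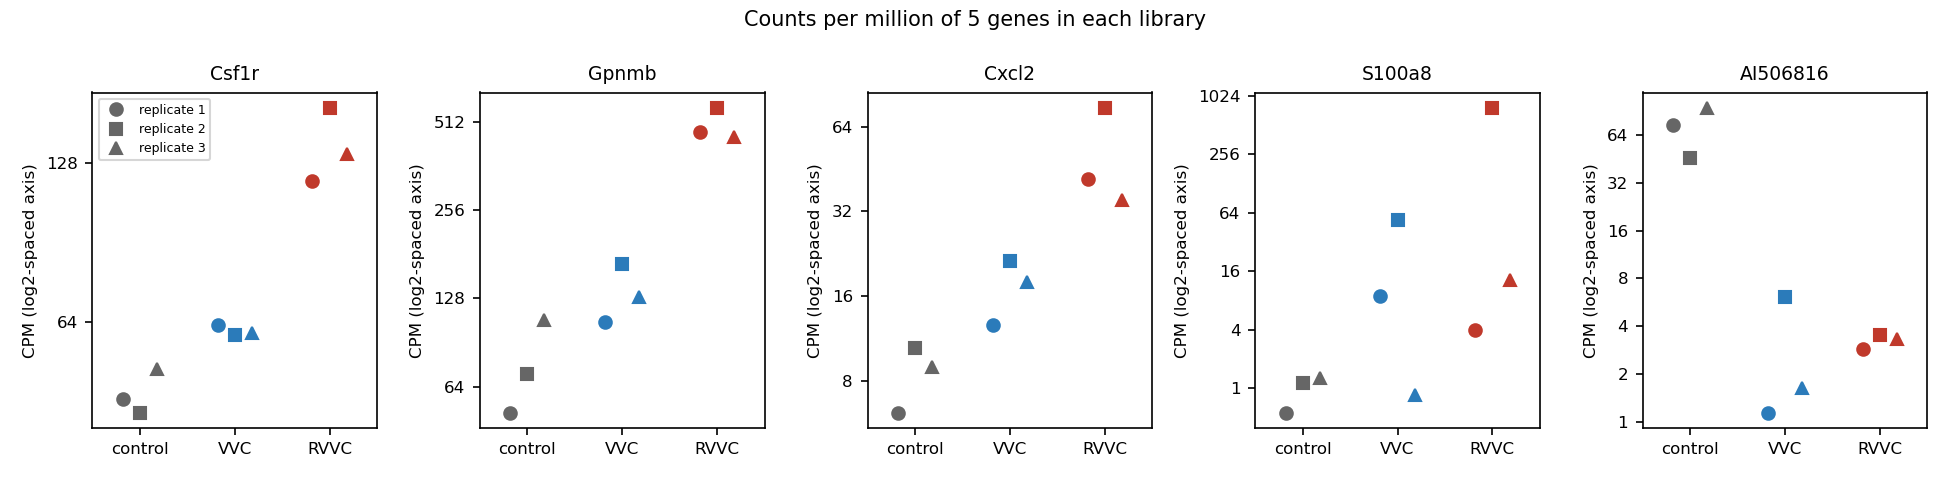
CPM of Csf1r, Gpnmb, Cxcl2, S100a8 and AI506816 (vertical axes, log2-spaced) in each library of the 3 groups (horizontal axes), with symbols for replicates. All 3 RVVC libraries lie above all others for Csf1r, Gpnmb and Cxcl2, and all 3 control libraries above all others for AI506816. S100a8 is far higher in RVVC replicate 2 than in the other RVVC libraries.

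The macrophage and monocyte list rose in RVVC against control, with a median log2 fold change of 1.45 over 19 members, 16 of them positive (adjusted p = 9.9e-25 by camera, and adjusted p = 0.076 with an estimated correlation). By fry its adjusted p was 0.047. Over all genes 0 members passed, and 11 passed adjusted over the list alone. Fcgr3, an antibody receptor, Cd68, a lysosomal macrophage protein, and Ms4a7 stood at 2.17 ± 0.34, 1.77 ± 0.28 and 1.38 ± 0.19. The pan-leukocyte gene Ptprc stood at 0.93 ± 0.37.

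Chemokines that draw neutrophils and monocytes rose by a median of 1.96 with 12 of 14 members positive, and this call held with an estimated correlation (adjusted p = 2.0e-11, and adjusted p = 0.035 with an estimated correlation). Cxcl2 averaged 50.5 ± 21.2 against 8.56 ± 2.20 CPM (2.56 ± 0.37), Ccl4 21.4 ± 2.23 against 0.879 ± 0.446 CPM (4.60 ± 0.88) and Ccl3 22.9 ± 5.28 against 1.59 ± 0.983 CPM (3.85 ± 0.92). Adjusted over the list alone 3 members passed, and over all genes 0. Cxcl1 and Cxcl5 stood at 1.14 ± 0.40 and 4.47 ± 1.78. Matrix metalloproteinase and wound healing genes rose by a median of 0.68 with 14 of 17 positive (adjusted p = 3.5e-06, and adjusted p = 0.035 with an estimated correlation). For that list 1 member passed adjusted over the list alone and 0 over all genes, and its median was 0.19 among genes with a mean FPKM of at least 5 and 0.42 without control replicate 2. These were the only calls of the 39 lists that held with an estimated correlation, and fry gave adjusted p of 0.037 for the chemokines and 0.019 for the metalloproteinases.

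Neutrophil markers rose by a median of 1.77 in RVVC against control (adjusted p = 0.10 with an estimated correlation), with Clec4d at 2.94 ± 0.53, Csf3r at 3.02 ± 0.89, Fpr2 at 2.61 ± 0.91 and Trem1 at 4.67 ± 1.62. The median was 1.15 without RVVC replicate 2. S100a8 averaged 262 ± 440 CPM, carried by RVVC replicate 2 at 770.4 CPM against 3.92 and 13.1 in the other RVVC libraries, and its log2 difference of 8.06 ± 2.45 did not pass. S100a9 stood at 7.81 ± 2.45, Il1b at 3.07 ± 0.74, Lcn2 at 2.42 ± 1.31 and Il17a at -0.43 ± 1.90. Without RVVC replicate 2 the log2 differences were 3.11 for S100a8, 3.18 for S100a9, 1.56 for Lcn2, 2.59 for Cxcl5, 1.58 for Csf3r and 2.55 for Trem1. All Il17a reads in RVVC came from that library, so the fit without it does not measure the size of a difference for Il17a. Il17a turned to 0.10 and 0.15 without RVVC replicate 1 or 3. Interferon response genes rose by 0.96 (adjusted p = 0.31 with an estimated correlation), with Ifit3, Rsad2, Isg15 and Oasl1 between 2.02 and 2.83. Without RVVC replicate 2 the interferon median was 0.46, with Ifit3, Isg15 and Oasl1 at 1.24, 0.77 and 1.24. The antimicrobial, IL-1, complement, MHC class II and oxidative stress lists rose by 1.57, 0.81, 0.43, 0.55 and 0.25, with adjusted p of 0.31, 0.20, 0.10, 0.20 and 0.20 with an estimated correlation. Without RVVC replicate 2 the antimicrobial, IL-1, MHC class II and oxidative stress medians were 0.12, 0.39, 0.25 and 0.11, and without RVVC replicate 3 the complement median was 0.08. The fungal recognition list (0.47) and the IL-17 and IL-22 list (0.37) had adjusted p of 0.43 and 0.40 with an estimated correlation, and both calls were lost without control replicate 1 (adjusted p = 0.13 and 0.083) and without RVVC replicate 2 (adjusted p = 0.28 and 0.66). Mitochondrially encoded genes (0.24) and smooth muscle genes (0.66) were called higher too, at 0.66 and 0.53 for the adjusted p with an estimated correlation. The mitochondrial call was lost without control replicate 1 or RVVC replicate 3 (adjusted p = 0.67 and 0.21), and the smooth muscle call without control replicate 2, RVVC replicate 1 or RVVC replicate 3 (adjusted p = 0.074, 0.11 and 0.072).

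Immediate early and heat shock genes, which respond to stimulation and handling within minutes, fell in RVVC against control by a median of 1.31 log2, with all 22 members negative (adjusted p = 2.5e-21, and adjusted p = 0.090 with an estimated correlation). Over all genes 0 members passed, and 11 passed adjusted over the list alone. Fos averaged 379 ± 304 against 2101 ± 844 CPM (-2.47 ± 0.58), and Zfp36, Ier2 and Junb stood at -2.18 ± 0.42, -1.80 ± 0.34 and -1.54 ± 0.31. Skeletal muscle genes had a median of -4.25 (adjusted p = 0.31 with an estimated correlation), which became -1.12 without control replicate 3, and the call was lost with array weights (adjusted p = 0.48). Myh4 and Pvalb had 0 counts in RVVC and were at least 5489-fold and 1655-fold lower against a floor of 3 counts in a library. Tnnc2 and Atp2a1 stood at -8.63 ± 2.5 and -8.40 ± 2.47. These values rest on control replicate 3: without it the bounds were 54.1-fold for Myh4 and 16.5-fold for Pvalb, and Tnnc2 and Atp2a1 stood at -2.87 and -1.80. Cell cycle genes fell by 0.80 with all 28 members negative (adjusted p = 0.53 with an estimated correlation), with Mki67 at -0.93 ± 0.84, or -0.51 without control replicate 3, and the list median was -0.51 without control replicate 3 and -0.52 without RVVC replicate 3. Erythrocyte genes had a median of -1.87, or -1.83 with the member at 0 set at its bound (adjusted p = 0.31 with an estimated correlation). The keratins Krt1, Krt5 and Krt13 and Esr1 stood at -0.96 ± 2.53, -0.47 ± 1.61, -0.22 ± 1.66 and 0.40 ± 0.32. The keratins turned to 4.83, 1.34 and 1.85 without control replicate 3, Krt13 also to 0.15 and 0.098 without RVVC replicate 1 or 3, and Krt5 and Krt13 to 0.87 and 0.94 with limma on log2(FPKM + 1). Esr1 was 0.62 without control replicate 1, 0.66 without RVVC replicate 2 and 0.20 without RVVC replicate 3, and the cornified envelope list did not pass (adjusted p = 0.20).

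**Figure D3:**
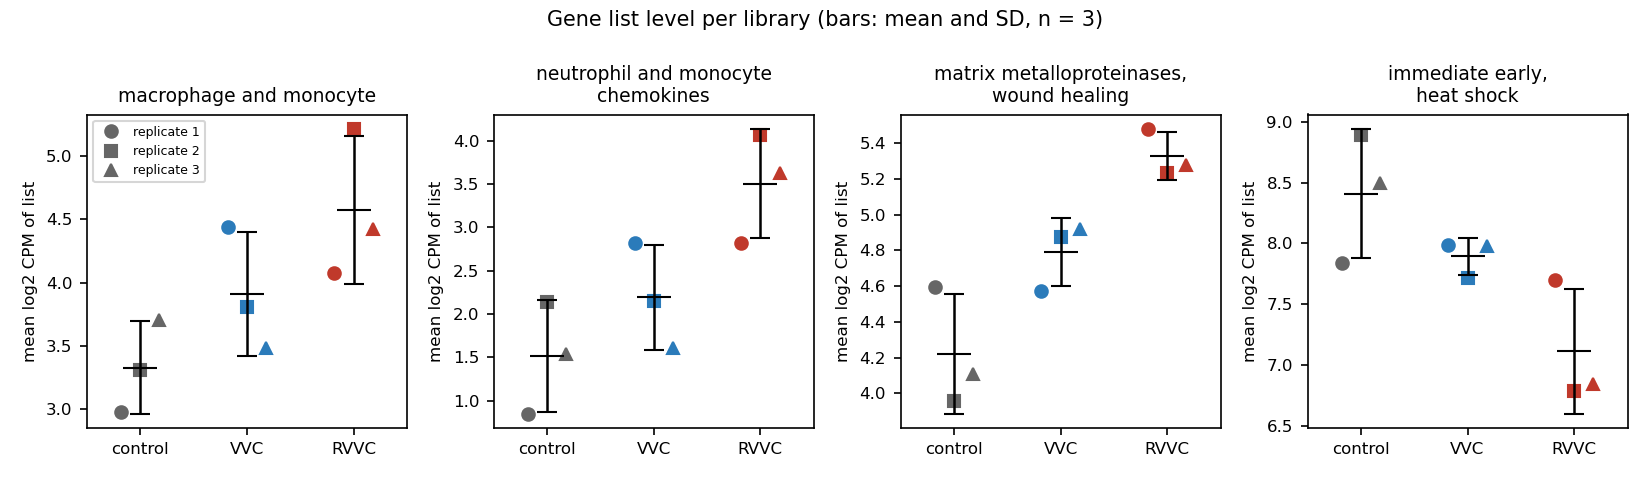
Mean log2 CPM of 4 gene lists (vertical axes) in each library of the 3 groups (horizontal axes). Symbols mark replicates and bars the mean and SD of 3 libraries. Chemokine levels are 1.51 ± 0.648 in control, 2.19 ± 0.606 in VVC and 3.51 ± 0.633 in RVVC, and immediate early levels are 8.41 ± 0.533, 7.89 ± 0.151 and 7.11 ± 0.512.

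RVVC against VVC asks which genes differ between the 2 models. Macrophage genes again led: Csf1r averaged 138 ± 22.8 CPM in RVVC and 61.5 ± 1.40 in VVC, a log2 fold change of 1.17 ± 0.16 (SE, n = 3). Mpeg1, Ms4a7 and Gpnmb stood at 1.24 ± 0.19, 1.2 ± 0.19 and 1.89 ± 0.31. Adgre1, which encodes a macrophage surface antigen, averaged 68.0 ± 12.1 against 19.3 ± 6.09 CPM (1.82 ± 0.31), and Fcgr3 stood at 1.87 ± 0.33. Each was higher in all 3 RVVC libraries than in any VVC library, and 7.17% of all genes tested did not overlap between these groups, where chance gives 10%. The smallest p among lower genes belonged to Stk32b (-4.03 ± 0.87), Nlrc5 (-0.98 ± 0.24), Myh3, which had 0 counts in RVVC and was at least 5.55-fold lower, and Itih4 (-2.01 ± 0.52).

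edgeR called 0 genes in RVVC against VVC, with a smallest adjusted p of 0.86. At an unadjusted p under 0.05 there were 543 genes, 267 higher and 276 lower, where chance gives 1069. DESeq2 called 65 genes, 42 higher and 23 lower, 6 of them on the macrophage list, a count that 4 of the 10 splits of the 6 libraries reached, and limma on log2(FPKM + 1) called 0. Fitted on the 6 libraries alone, edgeR called Saa3 and Marco higher (adjusted p = 0.0095 and 0.032), both named after their values were seen.

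The macrophage list rose in RVVC against VVC by a median of 1.03, with 15 of 19 members positive (adjusted p = 1.3e-14, and adjusted p = 0.16 with an estimated correlation). Over all genes 0 members passed, and 8 passed adjusted over the list alone. Neutrophil markers rose by 2.19, with Clec4d, Fpr1, Csf3r and Fpr2 at 2.83 ± 0.53, 2.65 ± 0.90, 2.36 ± 0.87 and 2.40 ± 0.91, and chemokines by 1.06, with Cxcl2, Ccl4, Ccl3 and Cxcl5 at 1.54 ± 0.36, 1.86 ± 0.78, 1.93 ± 0.85 and 3.73 ± 1.72. Metalloproteinase and wound healing genes rose by 0.56, and all 3 of these lists had an adjusted p of 0.15 with an estimated correlation. Without RVVC replicate 2 the neutrophil and chemokine medians were 1.09 and 0.44, and the metalloproteinase call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.15). S100a8 stood at 3.63 ± 1.99, which became -1.31 without RVVC replicate 2. S100a9 (4.13 ± 2.06) became -0.51 without that library, and Il1b stood at 2.05 ± 0.71, or 1.10 without it. Cxcl5, Csf3r and Fpr2 were 1.85, 0.92 and 1.54 without RVVC replicate 2. Lcn2 stood at -1.03 ± 1.25, and turned to 0.99 without VVC replicate 3. Cxcl1, Ptprc, Mki67, Il17a and Esr1 stood at 0.52 ± 0.39, 0.41 ± 0.37, -0.75 ± 0.83, -0.96 ± 1.91 and -0.06 ± 0.32, and Krt1, Krt5 and Krt13 at 0.61 ± 2.51, 0.60 ± 1.61 and 0.11 ± 1.66. Without RVVC replicate 2 the keratins turned to -4.76, -0.39 and -1.13, Esr1 to 0.20, and Ptprc was 0.10. Mki67 turned to 0.40 without VVC replicate 1, Il17a to 0.27 and Krt13 to -0.20 without VVC replicate 2, and Krt13 to -0.50 without VVC replicate 3. Cxcl1 was 0.33 without VVC replicate 1 and 0.81 without VVC replicate 2.

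Adipocyte genes fell in RVVC against VVC by a median of 2.02 with 12 of 13 members negative, among them Cfd (-2.65 ± 0.97), Retn (-2.48 ± 0.94), Cidec (-2.40 ± 0.95) and Adipoq (-2.44 ± 1.02). Skeletal muscle genes fell by 2.76 with all 20 negative, among them Myh2 (-5.97 ± 1.99), Mb (-4.62 ± 1.90), Myh1 (-2.95 ± 1.31) and Myh4, which had 0 counts in RVVC and was at least 61.7-fold lower. Both lists had an adjusted p of 0.27 with an estimated correlation, and the adipocyte median was -0.96 without VVC replicate 3 and -3.10 without RVVC replicate 3. Without VVC replicate 3, Retn and Adipoq were -1.62 and -1.37, without RVVC replicate 3, Cfd, Cidec and Adipoq were -4.13, -3.67 and -3.87, and without RVVC replicate 2, Mb was -7.52. Immediate early and heat shock genes fell by 0.67 with 21 of 22 negative (adjusted p = 0.25 with an estimated correlation), with Fos, Zfp36, Junb and Dusp1 at -1.60 ± 0.56, -1.09 ± 0.41, -0.78 ± 0.31 and -1.16 ± 0.45, and Fos at -2.5 without RVVC replicate 1. Camera with a preset correlation called 16 lists in all, 9 higher and 7 lower. The others were, higher, oxidative stress (0.42), cell junctions (0.39), fungal recognition (0.38), antimicrobial peptides and alarmins (0.35) and the IL-17 and IL-22 pathway (0.35), and, lower, erythrocyte (-2.62), mast cell (-1.39), B cell (-1.29) and mitochondrial genes (-0.44). Their adjusted p with an estimated correlation lay between 0.27 and 0.76, and the list counts with an estimated correlation and by fry were both 0. Without RVVC replicate 2 the antimicrobial, cell junction and fungal recognition medians turned to -0.95, -0.25 and -0.05, and these calls and those of the IL-17 and B cell lists were lost (adjusted p from 0.26 to 0.98). Without VVC replicate 2 the mitochondrial and mast cell calls were lost (adjusted p = 0.82 and 0.13), and without VVC replicate 1 the erythrocyte call (median -0.82, adjusted p = 0.12). The median, mean and test of each list called in the 3 comparisons had the same sign. As many called lists were reached by 8, 5 and 9 of the 10 splits in VVC against control, RVVC against control and RVVC against VVC.

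Fold changes against control in VVC and in RVVC correlated across the 21384 genes with r = 0.54, where genes are not independent replicates. Unchanged groups simulated against the same 3 control libraries gave r = 0.50 ± 0.012 (SD over 20 simulations), and a covariance of 0.43 ± 0.015 against 0.46 observed. The simulations drew each gene independently, so these SDs, and those below, leave out variation that genes share. With 1 library left out in turn, the observed r varied with an SD of 0.11. The SD of 0.012 therefore does not measure how far the observed r lies from that of unchanged groups. At an unadjusted p under 0.05, 125 genes were higher in both comparisons and 102 lower in both. The simulations, which also share the controls, gave 165 ± 11.1 and 83.9 ± 8.56, but with 1001 and 998 genes under that p in VVC and RVVC where the data had 604 and 992, so the counts do not compare like with like. With disjoint controls, 1 control library for one group and the other 2 for the other, r ran from -0.16 to 0.081 over the 6 ways, with a mean of -0.062, where the simulations gave a mean of 0.025 ± 0.011. This comparison was added after seeing the data, and rests on a single control library on one side.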

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

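The limma fit on log2(FPKM + 1), edgeR's newer quasi-likelihood estimate, the cornified-envelope covariate and the disjoint controls were chosen after seeing the data; the other settings were planned. Over all settings, 2719 values of named genes kept their direction and their side of the threshold, 88 passed it where edgeR's did not and 54 reversed. Of the called lists' values 972 kept both, 85 no longer passed and 6 reversed. For lists the direction is that of camera's test, which can differ from the sign of the median. edgeR's gene count of 0 did not move in any of the 3 comparisons with median-ratio scaling, without a filter, with the newer estimate, with the covariate or with the replicate block. The replicate block gave 17, 19 and 17 called lists and a correlation of fold changes of 0.51. Replicate numbers did not pair the libraries: after removing group means, r between libraries of the same number ran from -0.44 to 0.42, and exceeded 0.1 in 2 of 9 pairs. Except where given, the cause of a change was not tested.

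In VVC against control, the gene count was 1 with limma on log2(FPKM + 1), with array weights and with no variance trend, and 21 with DESeq2. In RVVC against control it was 3 with limma on log2(FPKM + 1), with quantile normalization and with no variance trend, 1 with a pseudocount of 0.1 or 0.01 and with a mean FPKM of at least 5, 2395 with array weights and 242 with DESeq2. Leaving out 1 library gave 0 to 1. In RVVC against VVC it was 16 with array weights, 2 with only the groups compared and 65 with DESeq2. Array weights rested on 2 libraries, control replicate 2 (5.36) and RVVC replicate 3 (6.22), while control replicates 1 and 3, VVC replicate 1 and RVVC replicate 2 had weights from 0.37 to 0.38. With an estimated correlation the called lists numbered 0, 2 and 0. Leaving out 1 library gave 13 to 22, 18 to 25 and 15 to 21 lists. The correlation of fold changes was 0.77 with array weights and 0.41 to 0.68 with 1 library left out. With disjoint controls it was -0.084, -0.022 and -0.13 with control replicate 1, 2 or 3 alone against VVC, and -0.16, 0.081 and -0.056 with them alone against RVVC, where by construction no control library is shared.

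In VVC against control, Cxcl5 stood at -0.85 with array weights and -1.17 with the covariate, Il17a at -0.66 with the replicate block and -0.33 with the covariate, Krt13 at 0.017 with the block and S100a9 at -0.13 with the covariate. With 1 library left out, Krt5 ran from -2.73 to 0.75, Krt1 from -5.83 to 4.25, Mki67 from -1.35 to 0.34, Krt13 from -2.13 to 1.75, Cxcl5 from -0.44 to 1.28, Il17a from -0.72 to 1.10 and the cell cycle median from -1.33 to 0.13. In RVVC against control, Krt5 was 0.87 and Krt13 0.94 with limma on log2(FPKM + 1) and with no variance trend, 0.87 and 0.96 with a pseudocount of 0.1, 0.87 and 0.97 with 0.01, and 0.93 and 0.96 with quantile normalization; Krt13 was 0.17 with the covariate. With 1 library left out, Krt1 ran from -6.32 to 4.83, Krt5 from -1.46 to 1.34 and Krt13 from -1.47 to 1.85. Il17a ran from -7.07 to 0.15 in these fits. The value of -7.07 came from the fit without RVVC replicate 2, which held all Il17a reads of RVVC. That value therefore does not measure the size of a difference. The IL-17 and IL-22 pathway median was -0.19 with array weights.

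In RVVC against VVC, Krt1 was -0.031 with limma on log2(FPKM + 1) and with no variance trend, -0.10 and -0.11 with pseudocounts of 0.1 and 0.01, -0.13 with quantile normalization, -0.63 with array weights and -0.22 with the replicate block. Krt13 was -0.16 with the block and Esr1 0.17 with array weights. With 1 library left out, Krt1 ran from -4.76 to 4.83, Krt13 from -1.13 to 1.88 and Krt5 from -0.39 to 2.23. Esr1 ran from -0.26 to 0.20, Mki67 from -1.29 to 0.40 and Lcn2 from -1.89 to 0.99. S100a9 ran from -0.51 to 6.34, S100a8 from -1.31 to 5.73 and Il17a from -7.61 to 0.27. The value of -7.61 came from the fit without RVVC replicate 2, which held all Il17a reads of RVVC. That value therefore does not measure the size of a difference. The medians of antimicrobial peptides and alarmins ran from -0.95 to 1.04, of cell junctions from -0.25 to 0.80 and of B cell and plasma cell markers from -1.52 to -0.25, the last at 0.036 with array weights.

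Where 1 library was left out of a group, its remaining libraries are assumed to vary like those of the other groups. No list test was made under DESeq2. In simulated data at this size edgeR's test did not recover 2-fold changes, so single-gene changes of that size were not detectable by that test here. DESeq2 and limma were not run on the simulated counts.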

Other observations

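The tests of annotation terms and of explanations below were chosen after the results were seen. For the count of genes that separate control from the other libraries, the prediction is recorded as written before its outcome. The bounds for both tests of epithelium, and the lists in the one for macrophages, were changed after their values had been seen.

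Among KEGG terms in RVVC against control, camera at a preset correlation called 49 of 306 higher and 10 lower. The smallest p belonged to the Staphylococcus aureus infection term, with a median log2 fold change of 0.60 over 51 genes (adjusted p = 2.5e-13, and adjusted p = 0.17 with an estimated correlation). The lysosome term, the organelle in which cells break down what they take up, rose by a median log2 fold change of 0.24 over 119 genes (adjusted p = 9.8e-10, and adjusted p = 0.17 with an estimated correlation). The phagosome term rose by 0.21 over 148 genes (adjusted p = 2.0e-06, and adjusted p = 0.26 with an estimated correlation). In RVVC against VVC the ribosome term rose by 0.37 over 132 genes (adjusted p = 1.1e-10, and adjusted p = 0.90 with an estimated correlation). In VVC against control the smallest p belonged to the systemic lupus erythematosus term, at 0.58 over 102 genes (adjusted p = 2.0e-10, and adjusted p = 0.51 with an estimated correlation), and that term fell by 0.53 in RVVC against VVC (adjusted p = 2.7e-05, and adjusted p = 0.77 with an estimated correlation). KEGG terms called numbered 32 higher and 6 lower in VVC against control, and 10 and 5 in RVVC against VVC. Of 1085 Reactome terms, 50 were called higher and 17 lower in VVC against control, 53 and 29 in RVVC against control, and 33 and 66 in RVVC against VVC. Among Reactome terms in VVC against control, NoRC negatively regulates rRNA expression had the smallest p, with a median of 0.57 over 48 genes. HDACs deacetylate histones rose by 0.34 over 71 genes. Their adjusted p by camera were 7.0e-07 and 2.4e-05, and 0.96 for each with an estimated correlation. Which genes the systemic lupus erythematosus term shares with these terms was not examined, so its name alone does not show an immune change. With an estimated correlation 0 terms of either source were called in any comparison.

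Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. For edgeR's gene count the real value was 0, which any split reaches, so its 10 of 10 splits in each comparison say nothing; the highest other counts were 7, 1 and 0. For called lists, 8 of 10 splits gave as many as the real 15 in VVC against control (highest other 19), 5 of 10 as many as 18 in RVVC against control (highest other 27) and 9 of 10 as many as 16 in RVVC against VVC (highest other 22). For DESeq2, 9, 3 and 4 of 10 splits gave as many genes as the real 21, 242 and 65, with 1983, 1529 and 350 in the highest other. For the median of immediate early and heat shock genes, 3 of 10 splits gave one as large as the real 0.61 in VVC against control (highest other 0.76), and 1 of 10, the real one, in RVVC against control (1.31, highest other 1.25) and RVVC against VVC (0.67, highest other 0.57). The immediate early list was also picked after the results of the real grouping were seen, which favours the real split. Splits in which DESeq2 calls several times the real count point to a structure of the samples other than their groups. In the comparisons with control, the highest other split separated libraries with negative values on the first principal component from those with positive values. In RVVC against VVC it did not.

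Macrophage and monocyte markers were higher in RVVC, called by camera at the preset correlation but not with an estimated one (adjusted p = 0.076 against control and 0.16 against VVC; by fry 0.047 and 0.30), and 1 of 10 splits, the real one, gave a list median as large against each group: 1.45 against 0.77 in the highest other for control, and 1.03 against 0.81 for VVC. The macrophage list was picked after the results of the real grouping were seen, which favours the real split. The top list of each other split was not compared, so this rank does not exclude chance. Less epithelium in the RVVC libraries would raise other non-epithelial markers alike. Against control the macrophage level exceeded the mean shift of the 12 other lists of non-epithelial cell types by 1.58 ± 0.52 (SE). It did so by over 2 SE with any 1 library left out (1.09 without RVVC replicate 2). Of the 12 lists 7 fell, and erythrocyte markers shifted by -1.65 ± 0.51. The excess over 4 of these lists, used first, was 1.28 ± 0.60 and did not hold so. Because the lists were widened after that value was seen, the excess does not decide against less epithelium. Basal, junction, cornified, mucous and non-keratinised epithelial levels shifted by 0.32 ± 0.96, 0.40 ± 0.64, 0.49 ± 2.40, 0.22 ± 1.08 and 0.53 ± 1.65 against control. None was lower, but each shift was smaller than its SE, so less epithelium stays open. Against VVC the excess was 1.3 ± 0.51 but 1.44 ± 0.84 without RVVC replicate 3. Less epithelium therefore cannot be told apart there with 3 libraries per group, although adipocyte and skeletal muscle levels shifted by -1.84 ± 0.76 and -2.82 ± 0.61. The cornified level shifted by 0.49 ± 2.40 against control and -0.89 ± 2.27 against VVC, which left it little to explain as a covariate. With that covariate the macrophage medians were 1.47 and 1.09, a result nearly fixed in advance, so it does not decide on the keratinised state. The lowest macrophage medians with 1 library left out were 1.28 and 0.74, both still called at the preset correlation, so no single library carries the call made there. More macrophages in the RVVC tissue, or higher expression in those present, may account for it, and sampling, collection and cycle stage are not labelled and stay open.

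The cornified envelope level differed within each group; an unequal share of epithelium would move basal keratinocyte markers as much, and these ordered the 3 libraries as the cornified level did in every group. The cornified SD was 1.74, 1.95 and 10.2 times the basal SD in control, VVC and RVVC; only RVVC passes the limits from an F distribution at 0.05 for a single group (4.36 for a 1-sided and 6.24 for a 2-sided test), and at 0.05 divided over 3 groups it passes the first (7.68) and not the other (10.9). These limits treat lists measured in the same libraries as independent, so an unequal share cannot be told apart in any group. Sequencing depth would order the libraries, and in 5 of 9 within-group pairs the library with the lower total had the higher level. Stage of the oestrous cycle, which changes keratinisation of the vaginal epithelium, is a possible explanation, but no label gives it and no biological explanation was tested.

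AI506816 was lower in VVC and RVVC than in control. Reads from a neighbouring gene would lower a neighbour too, but among 8 tested genes within 200000 bp the one nearest to falling in both comparisons had log2 fold changes of -0.40 in VVC and -1.0 in RVVC. For chance among the genes tested, 39 of 84 splits of the 9 libraries into 3 and 6 gave at least as many genes as the real 1 that are at least 4 times higher in all 3, with 67 in the highest other. Some of these splits may follow tissue content that libraries of different groups share. The cut of 4 times also lies below the difference of AI506816 in mean CPM. The count therefore does not exclude chance and cannot show that chance gives a gene like this one. A strain or donor difference between the mice stays open, since no label gives the strain.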
